A study of Mus musculus with 6 samples.

How the data were processed

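The series holds 6 samples of 1 mouse cell type, 3 control and 3 forskolin, and groups and replicate numbers were taken from the sample titles. RNA was size-selected, tailed, tagged and hybridised by a service provider (LC Sciences), and each sample was stained with Cy3 or Cy5, per the labels. The control samples were 2 Cy3 and 1 Cy5, and the forskolin samples 1 Cy3 and 2 Cy5. The scanner files hold an intensity per spot, a mean density in 1 dye with the local background not subtracted, per the file headers. The scanner and its software are not given in the sources used here. The deposited series table holds 1 intensity per miRNA and sample, in whole numbers on a linear scale, with column medians of 10, 11 and 8 for control 1 to 3 and of 11, 11 and 10 for forskolin 1 to 3. Set against the spot values minus the empty spots of the same sample, its log2 values correlated across tested probes at 0.996 or above, so its background had been removed, and how the authors normalized it between samples stays unknown. It was used as an alternative. No per-sample column was left unused for lack of a label.

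Each array had 3968 spots, of which 669 were empty. The mean intensity of empty spots was 131.2, 192.1 and 200.1 in the Cy3 samples control 1, forskolin 2 and control 3, and 32.61, 31.63 and 34.93 in the Cy5 samples forskolin 1, control 2 and forskolin 3. The highest spot of any sample read 58809, and no value repeated at a ceiling. A probe counted as detected where the mean of its 5 spots exceeded the mean of the empty spots by over 3 times their SD. Signal over background limits what can be measured on an array, and the number of arrays limits the precision.

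Spot intensities were corrected by normexp with an offset of 50 over all spots, the 5 spots of a probe were averaged, and log2 values were quantile-normalized between the 6 samples over the 599 probes (limma 3.58.1 in R 4.3.3). Quantile normalization gives a probe of the same rank the same value, so a few of the brightest probes have an SD of 0 within a group. Fold changes are on the scale of intensity plus offset and understate changes of dim probes. Probe names are those of the array design and follow an older style of naming in which a star marks the passenger strand. Closely related miRNAs can hybridise to each other's probes, so members of a family are not independent measurements.

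The main test was limma's lmFit and eBayes on 167 probes with a term for the treatment and a term for the dye, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is the coefficient for forskolin in that fit and differs from the plain difference of group means, since the dye is unbalanced. The gap had a median of 0.036 over tested probes and a maximum of 0.32 (miR-29c), and the sign differed for 4 of them, among them miR-30e and miR-709. P-values are two-sided. miRNA lists were tested with camera at its preset correlation of 0.01, adjusted over the 13 lists with at least 3 tested probes. The 24 lists were fixed before the data were examined and are named smooth muscle, striated muscle, muscle contraction, renin lineage, CREB and cAMP linked, let-7, miR-17/miR-92a and paralogs, miR-15/16, miR-29, miR-30, miR-23/27/24, miR-99/100/125, p53, hypoxia, inflammation and stress, mesenchymal, Dlk1-Dio3, Sfmbt2, RNA quality, epithelial, kidney tubule, endothelial, blood and neural. The rule for naming miRNAs was fixed at the same time. It takes up to 12 of the largest rises and 12 of the largest falls past the threshold, or else the 10 smallest p-values if under 10 passed. It adds every probe of miR-330, miR-125b, miR-132, miR-212, miR-143, miR-145, miR-21 and miR-181a, the 5 brightest probes, up to 4 tested probes per list by smallest p, and up to 3 detected probes per list of another cell type. Names outside it were chosen after their values were seen.

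The design text places 1 replicate on each array. Deviations from the group means correlated between the control and forskolin samples of the same number, at 0.397 for number 1, 0.473 for number 2 and 0.359 for number 3. Single spots over 1 log2 unit away from the other spots of their probe were also shared. The 3 pairs of the same number shared 16 such spots, and the 12 other pairs of samples shared 0. The 2 samples of a number carried opposite dyes, so they were taken to come from 1 chip, a pairing that rests on these data and not on the labels. The fit with the replicate number as a block and the dye term leaves 1 residual degree of freedom per probe, and limma then gave every probe the same spread. The standard error of a log2 fold change was 0.30 for each probe in that fit. Standard errors printed in the results are those of the main fit, also beside adjusted p-values of the block fit.

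The steps were tested on simulated data with known changes. Arrays were drawn 20 times on the real layout, levels and background, with 20 probes changed by 2-fold and 20 by 4-fold in the comparison of forskolin with control, over a mean of 176.2 tested probes. The main fit recovered 53.7% of the 2-fold and 97.1% of the 4-fold changes, and 2.07% of its calls were false. With the replicate block the shares were 83.0% and 96.3%, with 8.30% of calls false, above the nominal share. Every simulated probe had the same spread, as that block fit assumes, so the false share may be higher for real probes, whose spread differed. The median fitted log2 fold change was 0.764 of the simulated one at 2-fold and 0.812 at 4-fold. In 20 simulations with the miR-17/miR-92a list shifted, over 167 probes, the list test found it 20 times and called 0 of 240 other lists, with the preset and with an estimated correlation alike. Simulated noise was independent between probes, so this does not cover lists whose members are correlated. In the real data the estimated correlation was 0.49 for the let-7 list, 0.59 for the muscle contraction list and -0.012 for the miR-17/miR-92a list.

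Alternatives covered the normalization, the background correction, the source of the values, the filter on dim probes, the dye term, the block, the averaging of spots, the spread model, the thresholds, the list tests and leaving out each sample. A further 4 kinds were added after seeing the data, namely normexp fitted on the empty spots, loess between the dyes of a chip, leaving out both samples of a number, and detection against the dimmer miRNA probes. Gene neighbours came from a RefSeq table of assembly GRCm38.p6 and served only to tell which miRNA genes lie near each other or near Hox genes, with 539 of the 599 probes matched to a miRNA gene. No coordinates are given, since the array names no build. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.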

Results

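MicroRNAs were profiled in cultures of arteriolar smooth muscle cells (aSMCs) from mouse kidney, a primary line descended from cells that once made renin, the protease that starts the angiotensin cascade. The line was at passage 7, and the title of the series gives the induction of renin as the purpose of the treatment. The 3 forskolin cultures received 10 µM forskolin, an activator of adenylyl cyclase, with 100 µM IBMX, an inhibitor of the phosphodiesterases that degrade cyclic AMP, for 24 h. They received 10 µM forskolin again for 30 min before harvest. The 3 control cultures were untreated, and no vehicle is named in the labels. Each culture was grown and harvested independently, per the design text. RNA of each culture was hybridised to a microarray with 599 mouse miRNA probes, each spotted 5 times. Of these, 151 probes were detected in all 6 samples and 167 in all samples of at least 1 group, and the 167 were tested. The control samples had 162, 166 and 225 detected probes, and the forskolin samples 175, 585 and 197. The count of 585, in forskolin sample 2, fell to 178 when the background was taken from the dimmer miRNA probes in place of the empty spots. The number of arrays limits the precision of every value.

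The question of the comparison was which miRNAs of these cells differ after the treatment with forskolin and IBMX. miR-218 was 6.18-fold higher in forskolin cultures, and miR-196a, encoded next to Hox genes, was 3.89-fold higher. miR-30c was 2.92-fold higher, and miR-30a*, the passenger strand of miR-30a, was 2.61-fold higher. In the other direction, miR-20b was 3.19-fold lower, miR-17 2.99-fold lower, miR-20a 2.87-fold lower and miR-92a 2.20-fold lower. These last 4 belong to the miR-17/miR-92a cluster and its relatives, known as miRNAs that promote proliferation. miR-7a was 2.63-fold lower and miR-222, a miRNA linked to smooth muscle proliferation, was 2.15-fold lower.

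These 10 probes were all that passed an adjusted p of 0.05 in limma, 4 of them higher and 6 lower, and 32 passed an unadjusted p of 0.05. miR-218 (target UUGUGCUUGAUCUAACCAUGU) went from a log2 intensity of 7.70 ± 0.16 in controls to 10.33 ± 0.76 in forskolin cultures (SD, n = 3 each). Its log2 fold change was 2.63 with a standard error (SE) of 0.41 and an adjusted p of 0.0156. miR-196a (target UAGGUAGUUUCAUGUUGUUGGG) had a log2 fold change of 1.96, SE 0.29, at an adjusted p of 0.0142. It went from 11.84 ± 0.28 to 13.86 ± 0.40 (SD, n = 3). miR-30c (target UGUAAACAUCCUACACUCUCAGC) went from 11.74 ± 0.05 to 13.27 ± 0.13 (SD, n = 3), with a log2 fold change of 1.55, SE 0.20, and the same adjusted p as miR-196a. miR-30a* had a log2 fold change of 1.39, SE 0.29, at an adjusted p of 0.0425. All 10 probes differed in the direction of the call in 3 of 3 pairs of samples with the same replicate number, as 85 of the 167 tested probes did in one direction or the other. Of the tested probes, 39 had forskolin and control values that did not overlap, a share of 23.4% against 10% given by chance for exchangeable samples. Samples of a pair deviated together, so the 6 samples were not exchangeable. The 3 other splits that part all 3 pairs gave 3 to 9 such probes, and the highest of all other splits gave 29.

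**Figure D1:**
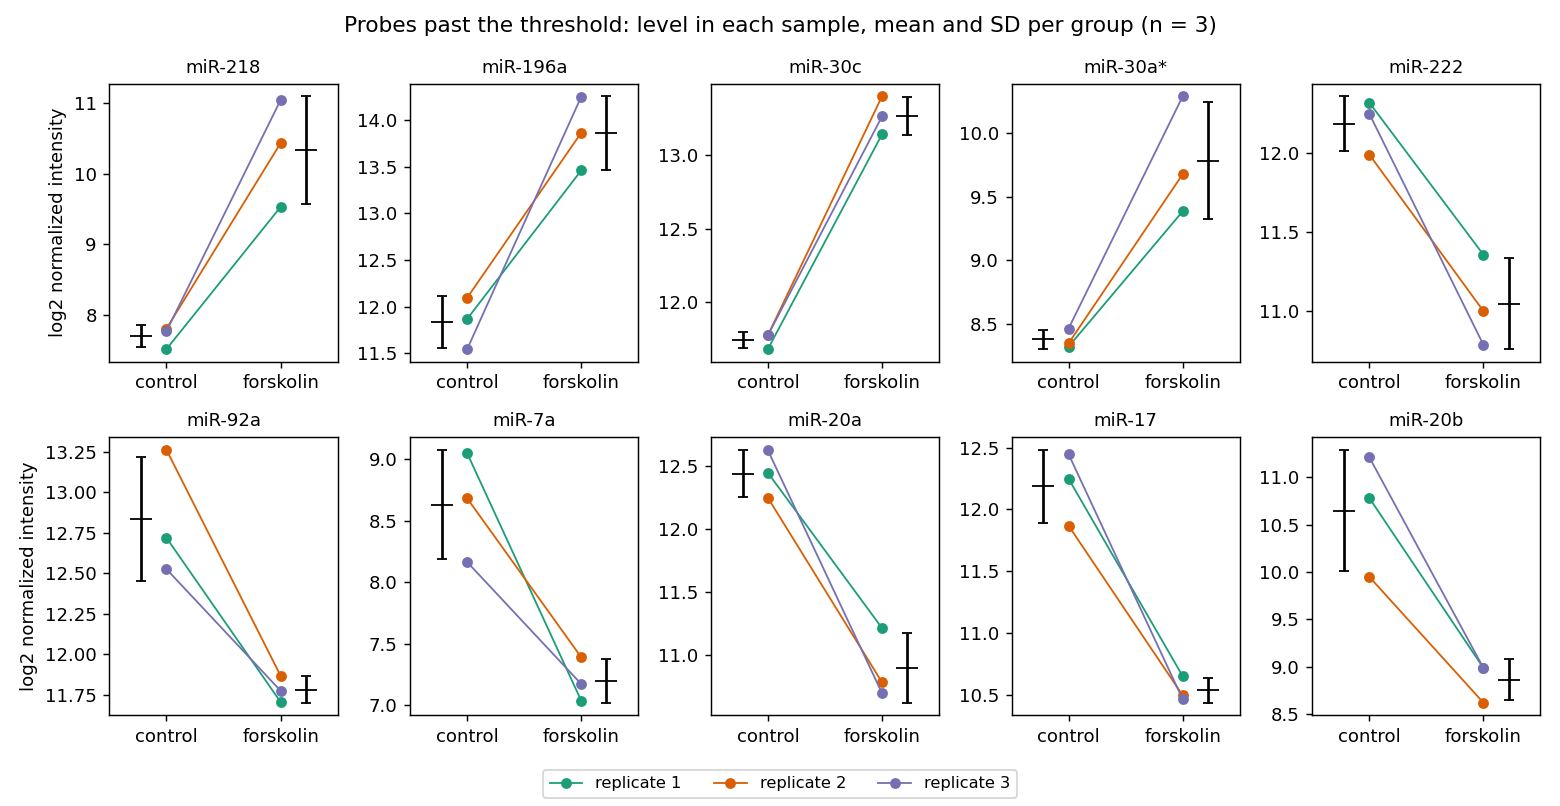
The normalized log2 intensity (vertical axis) of the 10 probes that passed an adjusted p of 0.05 is plotted for each control and forskolin sample, with lines joining samples of the same replicate number and black marks for the group mean ± SD (n = 3). For miR-218 the forskolin mean of 10.33 lies above the control mean of 7.70, and for miR-17 the forskolin mean of 10.54 lies below the control mean of 12.19.

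Samples with the same replicate number deviated together, as described with the processing. A fit with the replicate number as a block and the dye term gave 30 probes, 18 higher and 12 lower. All 10 probes were among the 30. Over 25 alternative fits the 10 probes passed in 7 (miR-92a) to 22 (miR-30c), with miR-222 in 10, and the log2 fold change of miR-92a reached -0.26 and that of miR-222 -0.37. The count of 10 was 0 without control 2 and 0 without forskolin 2, with 20 and 22 probes at an unadjusted p under 0.05. It was 3 without control 3, 0 without both samples of replicate 1 (17 at an unadjusted p under 0.05) and 24 without both of replicate 3. In the fit without replicate 3 limma gave every probe the same spread, as in the block fit with the dye term. In the fit without replicate 1 it did not, so the counts of 0 and 24 are not directly comparable. Control 2 was the only Cy5 control and forskolin 2 the only Cy3 forskolin sample. Without either, the dye-adjusted comparison rested on 1 dye, so a count of 0 there does not show that these samples drove the calls. The balance of higher and lower probes depended on the scaling: it was 7 and 0 with arrays scaled to the 75th percentile, 5 and 0 with no normalization, and 4 and 2 with loess normalization between the dyes of a chip.

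The miR-17/miR-92a cluster and its paralogs were lower as a group. All 11 tested probes had a negative log2 fold change, with a median of -1.14 and a range from -1.67 to -0.32, and 4 fell at an adjusted p under 0.05. Adjusted over the list alone 6 fell, and with the replicate block 7 fell over all tested probes. miR-17 (target CAAAGUGCUUACAGUGCAGGUAG) went from 12.19 ± 0.29 to 10.54 ± 0.10 (SD, n = 3), a log2 fold change of -1.58, SE 0.23, at an adjusted p of 0.0142. The log2 fold changes of miR-20a and miR-20b were -1.52, SE 0.25, at an adjusted p of 0.0157, and -1.67, SE 0.34, at an adjusted p of 0.0425. That of miR-92a was -1.14, SE 0.25, at an adjusted p of 0.0454. Values for miR-106a, -1.48 at an adjusted p of 0.0714, and miR-18a, -1.18 at an adjusted p of 0.0807, missed the threshold and passed it with the block. Of the members at the miR-106b locus, which also encodes miR-93 and miR-25, none passed, and miR-106b had a log2 fold change of -0.53, SE 0.25, at an adjusted p of 0.327. The group test (camera) gave an adjusted p of 1.68e-07 for the list. With an estimated correlation the camera adjusted p was 0.107, or 0.996 with the block as well, a value that every list tested had. The estimated correlation was -0.012, below the preset, so correlated members do not account for the higher p-value. With an estimated correlation camera is limited to the residual degrees of freedom, 3 in the main fit and 1 with the block. The self-contained test fry gave an adjusted p of 0.0298, or 0.595 with the replicate block. The list median was -0.42 with arrays scaled to the 75th percentile and -0.25 with no normalization, settings in which the median of all tested probes was 0.31 and 0.48.

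Probes of the miR-30 family, miRNAs abundant in kidney epithelium and also found in muscle and mesenchymal cells, were higher as a group. The 5 mature strands had positive fitted log2 fold changes, with a median of 0.54, though by the plain difference of group means 4 were higher and miR-30e was lower, at -0.07. Of the 5, 1 rose, miR-30c, or 2 adjusted over the list alone. The second was miR-30b, with 1.11, SE 0.29, at an adjusted p of 0.0714 over all tested probes and 0.00253 with the replicate block. miR-30a had 0.54, SE 0.30, and miR-30d and miR-30e had 0.13 and 0.07, none of them past the threshold. The camera adjusted p of the list was 0.0350, with an adjusted p of 0.425 with an estimated correlation and 0.109 with the replicate block. It also missed the threshold with cyclic loess (0.0522), scaling to the 75th percentile (0.0777), plain background subtraction (0.0687), the deposited series table (0.0858) and no dye term (0.0640). Without control 1, control 2, forskolin 1 or forskolin 2 the list's adjusted p was 0.101, 0.118, 0.0972 and 0.0716, and without both samples of replicate 1 it was 0.234. The median was 0.33 without forskolin 1 and 0.24 without both samples of replicate 1, and it was 1.12 at the 75th percentile, 1.29 with no normalization and 0.84 without both samples of replicate 3. Beside this group, 6 of 6 tested probes on the list of kidney tubule miRNAs, a marker list of another cell type, were also higher, with a median of 0.43 and the same camera adjusted p of 0.0350. Its adjusted p was 0.425 with an estimated correlation and 0.132 with the block. With other scalings it was 0.0522 (cyclic loess), 0.332 (median of detected probes), 0.307 (75th percentile) and 0.421 (no normalization). The list median was 0.15 with the median of detected probes, 0.69 at the 75th percentile and 0.86 with no normalization. In these settings the median of all tested probes was -0.24, 0.31 and 0.48. The list's adjusted p was 0.101 without control 1, 0.118 without control 2 and 0.0716 without forskolin 2. It was 0.0980 without both samples of replicate 1, where the list median was 0.27, and 0.0811 without both of replicate 3. Of the 6 probes, 1 rose, miR-30a*, and 1 also adjusted over the list alone. The list shares miR-30a with the miR-30 family, and miR-10a and miR-10a* with the smooth muscle list. Its miR-30a* comes from the same hairpin as miR-30a. miR-192, which is abundant in tubule cells, was detected in 1 of 3 control and 3 of 3 forskolin samples. Its level was 6.58 ± 0.11 in controls and 6.71 ± 0.08 in forskolin cultures (SD, n = 3), a log2 fold change of 0.12, SE 0.20, at an adjusted p of 0.795. miR-194 was detected in the same numbers of samples, with a log2 fold change of 0.33, SE 0.20, at an adjusted p of 0.428.

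**Figure D2:**
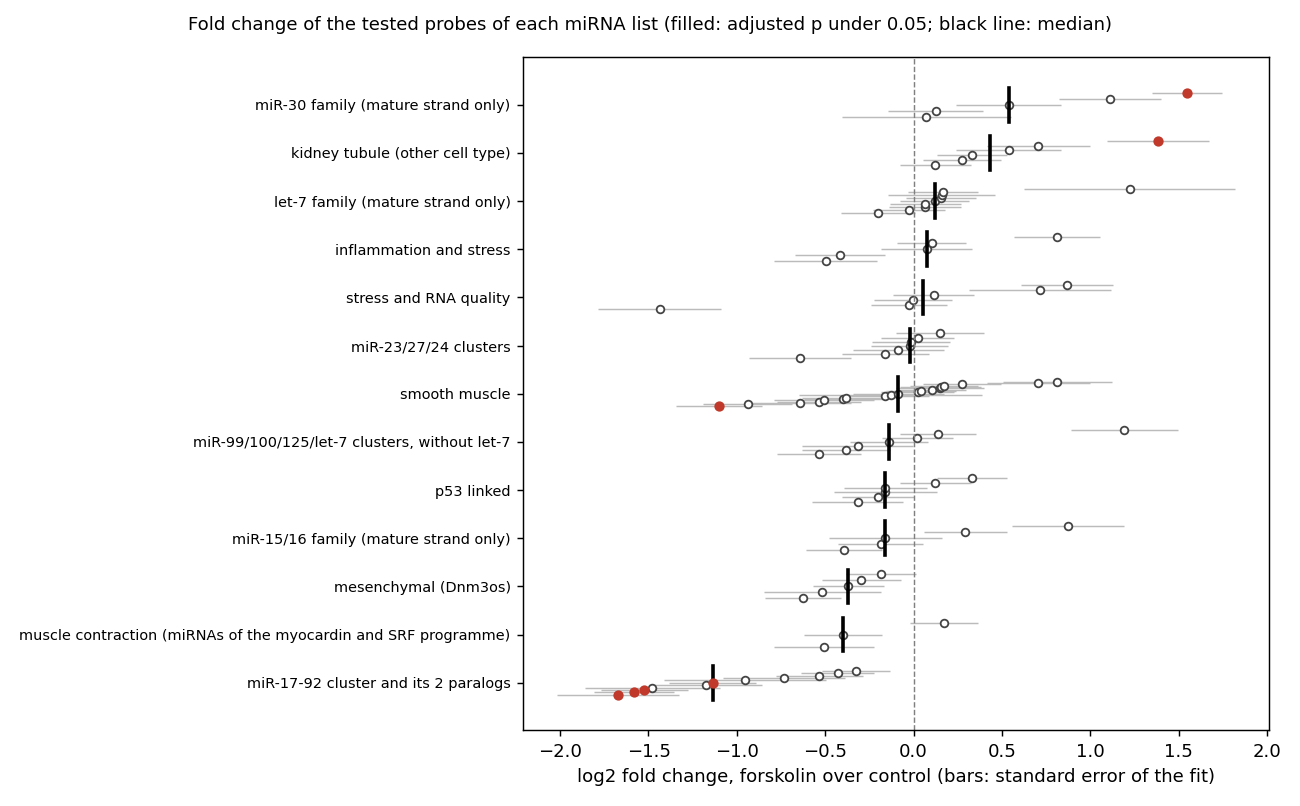
Log2 fold changes (horizontal axis, forskolin over control, with the standard error of the fit as grey bars) are plotted for the tested probes of each miRNA list with at least 3 of them. Filled points passed an adjusted p of 0.05 and black lines mark list medians, which run from -1.14 for the miR-17/miR-92a cluster and its paralogs to 0.54 for the miR-30 family.

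Smooth muscle miRNAs showed no common direction. Of 19 tested probes 9 were higher and 10 lower, with a median of -0.09 and a camera adjusted p of 0.725. miR-222 alone fell, at a log2 fold change of -1.10, SE 0.24, and an adjusted p of 0.0466, and none passed adjusted over the list alone. Its cluster partner miR-221 had -0.94, SE 0.25, at an adjusted p of 0.0798 and of 0.0147 with the replicate block. miR-10b had 0.81, SE 0.31, at an adjusted p of 0.191, of 0.0428 with the block and of 0.0606 with the block and no dye term. miR-10a had 0.71, SE 0.29, at an adjusted p of 0.251. miR-100 had -0.53, SE 0.24, and miR-27b* had -0.64, SE 0.29, and neither passed. miR-143 and miR-145, miRNAs of the contractile smooth muscle phenotype, were among the brighter probes. miR-143 was at 13.04 ± 0.04 in controls and 12.54 ± 0.45 in forskolin cultures, and miR-145 at 13.12 ± 0.14 and 12.69 ± 0.22 (SD, n = 3). Their log2 fold changes were -0.51, SE 0.28, and -0.40, SE 0.22, both at an adjusted p of 0.390. miR-145* had 0.17, SE 0.19. The list of muscle contraction miRNAs, which held these 3 probes, had a median of -0.40 and a camera adjusted p of 0.725, with none passing by either adjustment. miR-206 was the 1 tested probe of the striated muscle list, with a log2 fold change of -0.24, SE 0.34.

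Among miRNAs studied in renin cells, 2 probes could be tested and none passed by either adjustment. miR-125b-5p, the third brightest probe of the array, had a log2 fold change of -0.38, SE 0.25, at an adjusted p of 0.455. It was at 15.04 ± 0.18 in controls and 14.63 ± 0.29 in forskolin cultures (SD, n = 3). miR-181a had 0.33, SE 0.23, at an adjusted p of 0.512. miR-330 was not well above background in any control sample and passed detection in 1 forskolin sample, the one with 585 detected probes. miR-330* was detected in 2 control and 2 forskolin samples, at 6.59 ± 0.16 and 6.59 ± 0.09 (SD, n = 3), and was not tested. Of the passenger strands, miR-125b*, miR-181a-1*, miR-181a-2* and miR-21* were detected in no control sample and in 1 forskolin sample each, and miR-125b-3p in 1 sample of each group. On the list of miRNAs linked to CREB, the transcription factor that responds to cyclic AMP, 2 probes were tested, and both were higher. miR-132, a known CREB target, had a log2 fold change of 0.81, SE 0.24, from 9.69 ± 0.36 to 10.58 ± 0.13 (SD, n = 3), higher in 3 of 3 pairs. Its adjusted p was 0.102, adjusted over the list alone it was 0.0257, the 1 probe of the list to pass that way, and with the replicate block it was 0.0428. miR-132 is also on the list of inflammation and stress miRNAs, and adjusted over that list alone it did not pass, at 0.0642. miR-212, from the same transcript as miR-132, had 0.34, SE 0.20, at an adjusted p of 0.411, and was detected in 2 of 3 control and 3 of 3 forskolin samples.

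The other families of related miRNAs had no list past the threshold. All 9 let-7 family probes were detected, and let-7a and let-7c were among the 5 brightest probes with miR-21, miR-709 and miR-125b-5p. The let-7 median log2 fold change was 0.12 and the camera adjusted p 0.725. let-7a had 0.16, let-7b 0.17, let-7c 0.12 and let-7i -0.20, with none past the threshold, and miR-98 had 1.22, SE 0.60, at an adjusted p of 0.346 and of 0.000811 with the replicate block. On the mesenchymal list, which holds miR-199 and miR-214, all 5 probes were lower, with a median of -0.37, a camera adjusted p of 0.101 and none past the threshold by either adjustment. miR-199a-5p had -0.63, SE 0.22, miR-199b* -0.52, miR-214* -0.37 and miR-214 -0.30. The miR-15/16 list had a median of -0.16 but a mean of 0.09 and an upward camera test at an adjusted p of 0.901. miR-322 had 0.88, SE 0.32, at an adjusted p of 0.179 and of 0.0262 with the block, while miR-16 had -0.39, miR-15a 0.29 and miR-15b -0.19. The miR-99, miR-100 and miR-125 list, without let-7, had a median of -0.14 and a camera adjusted p of 0.901. In it miR-351 had 1.19, SE 0.30, at an adjusted p of 0.0714, 0.0411 adjusted over the list alone and 0.00111 with the block, and miR-99b had -0.32. The miR-23, miR-27 and miR-24 list had a median of -0.02 and a camera adjusted p of 0.901, with miR-23b at 0.15, miR-24 at -0.09 and miR-24-2* at -0.16. Apart from miR-351, no probe of these lists passed by either adjustment. In the miR-29 family miR-29a had -0.44, SE 0.26, and miR-29c -0.13, SE 1.04, with none passing.

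Stress lists gave no call over all tested probes. The p53 list had a median of -0.16 and a camera adjusted p of 0.901, with 2 tested probes higher and 4 lower. In it miR-194 had 0.33, miR-34a -0.32, miR-34c* -0.20 and miR-107 -0.16. miR-210, the hypoxia list's 1 probe, had -0.45, SE 0.27, at an adjusted p of 0.428. The list of inflammation and stress miRNAs had a median of 0.07 and a camera adjusted p of 0.901. Its miR-21, the brightest probe, had 0.10, SE 0.20, and miR-31 and miR-31* had -0.50 and -0.42. The list of probes tied to RNA quality, derived from tRNA or rRNA or rich in GC, had a median of 0.06 and a camera adjusted p of 0.901. Adjusted over the list alone, 1 of its probes rose and 1 fell. They were miR-1224, with 0.87, SE 0.26, at an adjusted p of 0.102 over all tested probes and of 0.0274 with the block, and miR-690, with -1.44, SE 0.35, at an adjusted p of 0.0688 and of 5.30e-05 with the block. miR-705 had 0.72, miR-762 0.11 and miR-709 -0.02. In the imprinted Dlk1-Dio3 cluster 1 of 72 probes was tested, miR-329, with -0.62, SE 0.32, at an adjusted p of 0.379. In the Sfmbt2 cluster and its relatives 2 of 44 were tested, miR-669c with 0.36, SE 0.31, and miR-467a with 0.12, SE 0.24.

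Markers of other cell types were mostly not well above background. No probe of the epithelial list, 12 on the array with the miR-200 family among them, of the endothelial list, 2 probes of miR-126, or of the blood list, 7 probes, was detected in all samples of a group. The neural list had 1 tested probe, miR-128, with a log2 fold change of -0.08, SE 0.27, at an adjusted p of 0.908. The kidney tubule list, given above beside the miR-30 family, was the 1 such list with several tested probes. As a technical comparison, the Cy5 and Cy3 samples were set against each other in the same limma fit. No probe passed an adjusted p of 0.05 for the dye, and 1 passed an unadjusted p of 0.05. The absolute dye coefficient had a median of 0.108 and a maximum of 0.95 log2 units. Both dyes were taken to share each chip, and this fit had no chip term, so dye differences could be missed.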

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

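Tests with loess between the dyes, normexp on the empty spots, both samples of a number left out and detection against the dimmer miRNA probes were chosen after the data were seen. All 10 probes past the threshold kept their direction in 25 alternative fits, and no named miRNA or list past the threshold reversed. Sign changes of values that passed in neither fit were not counted. The count of 10 probes was 30 with the replicate block and the dye term, 24 with the block alone, 22 with the replicate number as a random block and 18 with no dye term. It was 17 with a trended, robust spread, 19 at an adjusted p under 0.10 and 18 at an unadjusted p under 0.01. It was 5 with no normalization, 5 with the median of the spots, 4 with plain background subtraction, 6 with loess between the dyes and 1 with all 599 probes tested. With samples left out the count ranged from 0 to 24. It was 0 without control 2, without forskolin 2 and without replicate 1 (20, 22 and 17 probes at an unadjusted p under 0.05 in limma). It was 3 without control 3 and 24 without replicate 3. In the fit without replicate 3 limma gave every probe the same spread, so its count is not directly comparable with the 0 without replicate 1. The fits without 1 sample leave 2 residual degrees of freedom and those without 1 chip leave 1. Without control 2 or forskolin 2 the dye-adjusted comparison also rests on 1 dye. The count of 3 lists past the threshold was 1 with cyclic loess, 1 at the 75th percentile, 1 with either replicate block, 1 with fry and 0 with an estimated correlation (1 list at an unadjusted p under 0.05). It ranged from 1 to 3 with samples left out. The miR-17/miR-92a list passed in every camera fit with the preset correlation, at an adjusted p of 5.49e-05 or lower, but not with an estimated one, at 0.107. With the replicate block 20 more miRNAs passed, and the miR-30 and kidney tubule lists did not, and it changed no other list's call. The median log2 fold change of all tested probes was -0.01, but -0.24 with scaling to the median of detected probes, 0.31 at the 75th percentile and 0.48 with no normalization. Relative to that median, the median of the miR-17/miR-92a list was -1.12 with the main normalization and -0.73 with these 3. That of the miR-30 list was 0.55 and 0.81. Values in these 3 settings differ only by a constant per array, so the relative medians are the same by construction, not 3 separate results. The number of detected probes, 167, was 586 when detection on 1 array sufficed, of which 585 were detected in forskolin 2. The dye gave 0 probes with the main normalization, with cyclic loess and with scaling to the median, the last with 20 at an unadjusted p under 0.05. Except where the text names a reason, the cause was not tested. An offset of 1 was not run, since the scanner values still hold the background, and no slide or scan batch was run, since the files used here name none. Signal over background limits the dim probes, 432 of which were not tested.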

Other observations

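The tests of cross-hybridisation, of GC content, of scaling and of tubule cells, and the choice to look at miRNAs next to Hox genes, came after the results were seen. The tests of genomic neighbours and of hairpin arms were written down before their results. Besides miR-196a, 6 further tested probes belong to miRNAs encoded within 20 kb of a Hox gene, and all 7 were higher in forskolin cultures in 3 of 3 pairs, where 85 of the 167 tested probes had 3 of 3 pairs in one direction. The log2 fold changes were 1.96 for miR-196a, 1.75 (SE 0.92) for miR-196b, 0.88 (SE 0.33) for miR-615-3p, 0.81 for miR-10b, 0.71 for miR-10a, 0.27 for miR-10a* and 0.15 for miR-10b*. miR-196a passed the threshold, and 4 of the 7 passed with the replicate block and the dye term. With the block and no dye term miR-196b and miR-10b did not pass, each at an adjusted p of 0.0606. Their median of 0.81 lay at percentile 99.97 of 10000 random lists of the same size matched on level, and camera gave p = 0.000606, or p = 0.0661 with an estimated correlation. The group was noticed in these data, so these values describe it and do not test it independently.

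Of the 20 further miRNAs that passed with the replicate block and the dye term, 14 were higher and 6 lower, and 4 of the higher ones are named here. miR-322 and miR-351, encoded side by side, had log2 fold changes of 0.88 (SE 0.32) and 1.19 (SE 0.30). miR-181b had 1.02 (SE 0.25) and miR-689 had 1.72 (SE 0.50). These SEs are of the main fit, and with the block and the dye term the SE was 0.30 for every probe. With the block and no dye term miR-322 and miR-181b did not pass, at adjusted p of 0.186 and 0.0865, and miR-322 was lower in the forskolin sample of replicate 3 than in its control.

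Genomic neighbours were compared as pairs of tested probes of different hairpins within 10 kb whose sequences differ by over 6 edits. The hypothesis was that neighbours, often cut from 1 transcript, share their change. Over 52 pairs the mean absolute difference of log2 fold changes was 0.3, against 0.659 when fold changes were shuffled among probes (permutation p = 1e-05, the smallest that 100000 permutations can give). The 43 pairs outside the miR-17/miR-92a list gave 0.279 (permutation p = 1e-05). Arms of 1 hairpin differed by 0.445 on average over 24 pairs, against 0.659 (permutation p = 0.02). Shuffling ignores that neighbours are often alike in brightness and that pairs share probes, so the p-values may be too small. The shuffled mean of 0.659 was the same for clusters and arms, since values were drawn from all tested probes. Paired probes that changed little would differ less than that without sharing a change, and these comparisons cannot separate the 2. The arms differed at miR-30c, with 1.55 for the mature strand and 0.15 for miR-30c-2*, though miR-30c has a second hairpin.

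The fall of the miR-17/miR-92a cluster and its paralogs was set against technical explanations. Cross-hybridisation of miR-17 and its near copies as the whole cause is argued against by the tested members over 6 edits from every miR-17-like sequence. These 4 had a median log2 fold change of -0.691, and their median was negative on all 3 chips. They were miR-92a at -1.137, miR-19b at -0.953, miR-25 at -0.429 and miR-106b* at -0.324, and miR-92a alone passed the threshold. The 117 other tested probes within 2 percentage points of a member's GC had a median log2 fold change of -0.005 (95% bootstrap interval -0.0923 to 0.119). Members spread widely in GC, so this pool held most other tested probes and its median says little by itself. A GC trend is argued against by a slope of -0.0184 log2 units per 10 percentage points of GC over other tested probes. The list median depended on scaling, from -1.137 to -0.254 with no normalization, but scaling as the whole cause is argued against by a difference of -0.938 or lower from other probes of like level with quantile, cyclic loess, 2-colour loess and no normalization, with the list outside the 95% range of 10000 random lists each time. Cross-hybridisation among miR-17, miR-20a, miR-20b and miR-106a could still make 1 change appear several times, and a lower rate of proliferation under cyclic AMP is a candidate biological explanation that these arrays do not test.

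Of the 8 tested miR-30 strands 7 were higher by their group means, and miR-30e was higher only through the dye term of the fit. Cross-hybridisation with miR-30c is argued against for the passenger strands, at least 13 edits away, with a median of 0.952 over 3 that rests on miR-30a* and miR-30e*, which differ by 1 edit, while miR-30c-2* had 0.15. For the mature strands it stays a candidate explanation, since miR-30b, 3 edits away, had 1.11 and the 3 strands at least 6 edits away had a median of 0.126. GC content is argued against by a median of -0.026 over 67 other probes of like GC (95% bootstrap interval -0.186 to 0.121). The slope over other tested probes was 0.0132 log2 units per 10 percentage points of GC.

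More kidney tubule cells in the forskolin cultures cannot be told apart from a change within smooth muscle cells as the reason why miR-30 probes were higher. The tested tubule markers outside the miR-30 and smooth muscle lists, miR-192 and miR-194, had a median log2 fold change of 0.227. At mean levels of 6.65 and 6.75 they lay near the median of all miRNA probes, 6.31, where a small change can hardly be measured. Neither showed a large rise, with forskolin means of 6.71 and 6.90, while miR-30c had a log2 fold change of 1.55. The 12 probes of the epithelial list also lay near that median, at a highest mean level of 6.34. miR-10a, on both the tubule and the smooth muscle list, had 0.71.

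For the miRNAs next to Hox genes, GC content is argued against by a median of -0.037 over 72 other probes of like GC (95% bootstrap interval -0.16 to 0.069). Over other tested probes the slope was 0.0141 log2 units per 10 percentage points of GC. Cross-hybridisation within a sequence family stays open, since miR-196a and miR-196b differ by 1 edit, as do miR-10a and miR-10b, and the group was noticed because its probes were higher. A shared response of the Hox regions to forskolin and IBMX was not tested and stays open beside it.

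Other splits of the 6 samples into 3 and 3 were fitted with the dye term, which 9 of the 10 splits allow. The real split gave 10 probes and the highest other split 0, so 1 of 9 splits gave as many. For lists, the real split gave 3 and the highest other split 3, so 2 of 9 splits gave as many. The other one exchanges the control and forskolin samples of replicate 3, and like the real split it parts all 3 chips. With 9 splits no share under 0.05 can be reached.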
